A study of Zea mays with 4 samples.

How the data were processed

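The series holds 4 Affymetrix maize arrays of ear internode RNA from the inbred line F271, 2 at tassel emergence and 2 at early silking. Per the labels, the RNA was amplified and labelled with biotin, and the amounts were 290 and 440 ng at tassel emergence and 340 and 400 ng at early silking. The deposited values are log2 probe set summaries made with GCRMA, a method that subtracts background by probe sequence and normalizes between arrays, per the submitters' processing notes. No version of GCRMA and no test is given in the sources used here, and the log2 scale was read from the values, which run from 1.36 to 15.24. The labels do not say whether the replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. No pair of arrays shared a value in any tested probe set.

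Of 17734 probe sets, 113 controls were left out. A probe set was tested when its log2 value was above 4 on at least 2 of the 4 arrays, whichever the stage, which kept 10782 and left out 6839. Gene names came from the platform annotation, updated through gene identifiers to the symbols of the RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone. It gave 1 gene for 1452 probe sets, several genes for 1 and none for 16168, and 1060 of 1108 genes matched. The tested probe sets covered 800 genes. 1 probe set per gene, that with the highest mean, stood for the gene. 107 genes had several tested probe sets, and in 30 these differed in sign, in none of them with both signs at an unadjusted p under 0.05.

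Early silking minus tassel emergence was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05), without a term for the replicate number. The prior degrees of freedom were 1.95. A permutation of 1 gene over 2 against 2 arrays cannot give a p under 0.33. The 31 gene lists for wall, growth, stress and other tissues, matched by expressions on gene names, the filter, the tests and the rule for named genes were fixed before the data were examined. The 19 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, against the other named genes, since only these could belong to a list. The choice of that background was made after the data had been seen, and the result against all tested probe sets is given with the alternatives. camera with an estimated correlation, which has 2 residual degrees of freedom here, and fry, which tests whether a list's genes move one way on balance, were alternatives. Where both arrays of a stage were at or below a log2 value of 4, a fold is a bound, the other stage's mean against 4, or the values themselves are given.

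The rule for named genes took the 12 largest rises and 12 largest falls among genes with an informative name, an adjusted p under 0.05 and separate stages. Where fewer passed, the rest of the 12 were taken by the smallest unadjusted p and given as not past the threshold. In each list it took the 2 largest rises and the 2 largest falls past the threshold, and every such member of the monolignol, lignin polymerisation and both cellulose lists. Whatever their p, it took the member of each monolignol enzyme family with the highest mean and the genes named for the brown midrib loci, of which bm1 was found.

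The fit was tested on 10 simulated data sets of 10782 probe sets and 2 against 2 arrays with 200 changed probe sets and variances drawn from the fitted prior. At an adjusted p under 0.05 it recovered 68.3% of log2 changes of 4, 3.73% of changes of 2 and 0.149% of changes of 1, and 5.1% of unchanged probe sets had an unadjusted p under 0.05. camera over 800 simulated genes found a 5-gene list moved by -2 in 100% and by -1 in 85% of 20 data sets, with no list called where nothing was changed. Simulated genes were drawn independently, so these rates do not cover lists whose genes are correlated. The recovered shares hold for 200 changed probe sets of 10782, since the Benjamini-Hochberg adjustment depends on how many change. From the p-values of the measured data, an estimated 60.96% of tested probe sets were unchanged, though dependence between probe sets can distort that estimate. The simulation thus does not give the power for data like these. The alternatives were the replicate number as a block, other filters, quantile normalization, centred arrays, an intensity trend, 1 common variance, leaving out each array, 1 probe set per gene, all probe sets of a gene in the lists and a stricter threshold. Added after seeing the data were crossed pairs, the 3' minus 5' gap of control transcripts as a covariate, lists checked by name and the wider background.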

Results

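RNA from the ear internode, the stem segment that bears the ear, of the maize inbred line F271 was hybridised to 4 Affymetrix maize arrays. F271 is the less favourable parent of a recombinant inbred population, made with line F288, in which loci for lignin content and for the degradability of the cell wall had been mapped. The plants grew in an irrigated field in a hot, dry summer. Tassel emergence and early silking were each represented by 2 arrays, and the RNA amounts given in the labels ran from 290 ng to 440 ng. Values are log2 probe set summaries. Their medians over the 17621 probe sets without controls lay between 6.35 and 6.51. Precision is limited by the number of arrays. The tassel emergence arrays correlated at r = 0.933 across the 10782 tested probe sets and the early silking arrays at r = 0.967, while arrays of different stages correlated at 0.883 to 0.914. These correlations run across probe sets, which are not independent replicates. The SD of the difference between arrays was 0.83 within tassel emergence, 0.59 within early silking and 0.94 to 1.10 between stages.

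The single comparison, early silking minus tassel emergence, asked how expression in the ear internode differs between these stages in a line studied for its lignin and cell wall. Lists of genes for cellulose synthesis, tubulins and the monolignol pathway were lower at early silking with a preset correlation between genes. With an estimated correlation none of these 4 lists passed (adjusted p = 0.629 for both cellulose lists and tubulins, adjusted p = 0.683 for monolignol genes). That version has 2 residual degrees of freedom, so failing it does not tell whether the genes are too correlated for the calls. The 3' minus 5' gap of control transcripts differed between the stages by -1.63. The secondary wall cellulose list, with the cellulose synthases that build the thickened wall, was lower by a median of -2.27 on the log2 scale over 5 genes. The primary wall cellulose synthases were lower by a median of -1.10 over 6 genes, and the tubulin and actin-related list by -0.61 over 13 genes. The beta-tubulin gene tub4 went from 13.08 ± 0.09 (SD, n = 2) to 11.17 ± 0.001. The heat shock list and the vacuolar invertase gene ivr2 were also lower at silking, while the ribosomal protein and photosynthesis lists were higher, by medians of 0.49 and 0.55. With an estimated correlation these lists did not pass either (adjusted p = 0.804 for heat shock, adjusted p = 0.683 for ribosomal proteins, adjusted p = 0.808 for photosynthesis), and with the gap as a covariate the photosynthesis median was -0.04. No probe set passed an adjusted p of 0.05 among the 10782 tested (limma, smallest adjusted p = 0.0864). An unadjusted p under 0.05 was found for 2679, where chance gives about 539.1 on average. Probe sets on the same arrays are not independent, so that excess is not a test of stage. Adjusted over the 800 genes that the platform table names, with 1 probe set per gene, 28 passed, of which 22 were lower and 6 higher at early silking.

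**Figure D1:**
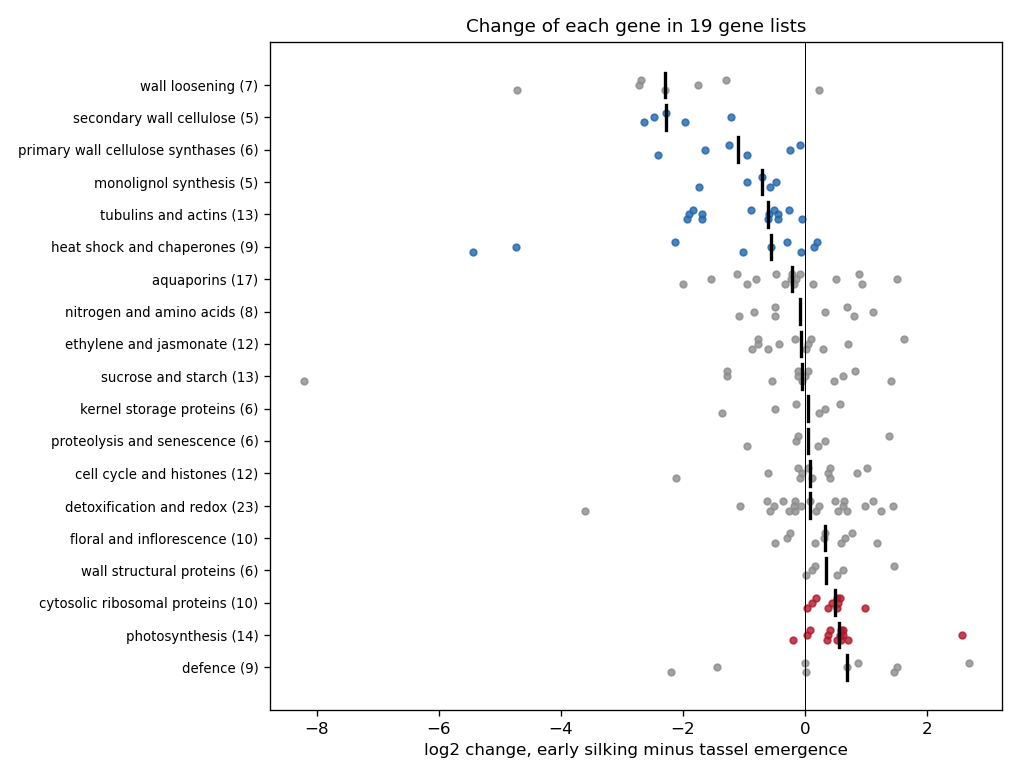
Fitted log2 change from tassel emergence to early silking of each measured gene (points), also below a log2 value of 4, in the 19 tested gene lists, with black bars at list medians and the number of genes after each name. Blue (lower) and red (higher) lists passed an adjusted p of 0.05 in camera with a preset correlation, and all 5 secondary wall cellulose genes lie below 0.

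All 5 measured secondary wall cellulose genes were lower at early silking and their stages did not overlap. The list fell relative to the other named genes (camera, adjusted p = 0.000108 with a preset correlation; adjusted p = 0.629 with an estimated correlation). bk2, brittle stalk2, a COBRA-like protein needed for cellulose in stem walls, went from 12.83 ± 0.36 (SD, n = 2) to 10.18 ± 0.14, a change of -2.65 with an SE of 0.26. The secondary wall cellulose synthases cesa11, cesa10 and CesA12 had log2 changes of -2.47, -2.27 and -1.97, and Bk2L3, a bk2-like gene, had -1.20. No member of any list passed over all probe sets, and the 5 genes here passed adjusted over the list alone. The cesa11 probe set is of a type shared by several transcripts. Of the 6 primary wall cellulose synthases, all were lower and 4 passed adjusted over the list alone. That list fell as well (adjusted p = 0.00229 preset, adjusted p = 0.629 with an estimated correlation). CesA-8 went from 10.21 ± 0.01 (SD, n = 2) to 7.80 ± 0.08, and CesA-2, CesA-6 and CesA-7 had changes of -1.64, -1.25 and -0.95. CesA-5 and CesA-3 were at -0.25 and -0.08 with overlapping stages. CesA-9, a cellulose synthase that the fixed list did not take in by name, went from 11.58 ± 0.01 (SD, n = 2) to 10.06 ± 0.01. CesA-4, also named as a cellulose synthase and not in that list, had -1.445 and passed when adjusted over the named genes. The CesA-4 probe set is of a type whose probes may also bind other transcripts.

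**Figure D2:**
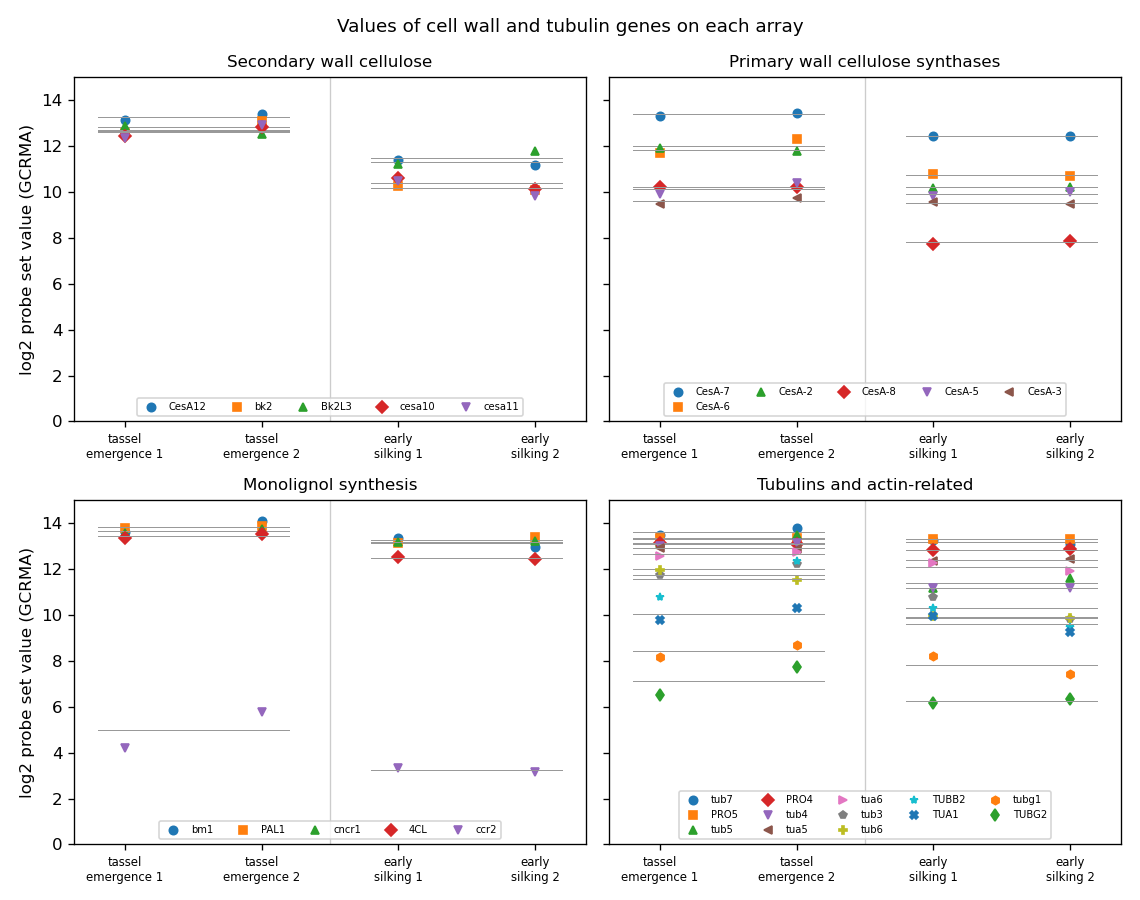
Log2 values of each gene of 4 lists on each of the 4 arrays, with grey lines at the stage means. In the secondary wall cellulose panel every gene has both tassel emergence values above both early silking values.

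The tubulin and actin-related list, structural proteins of microtubules and regulators of actin, had all 13 members lower, 11 of them without overlap (camera, adjusted p = 0.000108 preset, adjusted p = 0.629 with an estimated correlation). 4 members passed adjusted over the list alone. The beta-tubulins tub4, tub5 and tub6 had changes of -1.91, -1.93 and -1.83, and the beta-tubulin tub7 had -0.45. The alpha-tubulin tua6 had -0.58 and the profilin PRO5 -0.05. The monolignol list, enzymes that make the precursors of lignin, had all 5 members lower without overlap and a median of -0.70 (adjusted p = 0.0133 preset, adjusted p = 0.683 with an estimated correlation). 4CL, 4-coumarate:CoA ligase, went from 13.43 ± 0.14 (SD, n = 2) to 12.48 ± 0.08 and was the 1 member to pass adjusted over the list alone. bm1, the cinnamyl alcohol dehydrogenase gene of the brown midrib1 locus, had a change of -0.70 with an SE of 0.28 (limma, adjusted p = 0.223). PAL1, phenylalanine ammonia-lyase, and cncr1, a cinnamoyl-CoA reductase, had -0.57 and -0.47, and neither passed. ccr2, a second reductase of that kind, was near the floor, with values of 4.19 and 5.78 at tassel emergence and 3.33 and 3.16 at silking.

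The control probe sets of 5 maize transcripts measured a 3' minus 5' gap, which depends on RNA integrity and on the amplification and labelling of the RNA. The 3' end exceeded the 5' end by a mean of 4.57 and 2.88 on the log2 scale on the tassel emergence arrays and by 1.84 and 2.37 on the early silking arrays, so the gap moved with stage beside every gene group given here. In 4 of the 5 transcripts the stages did not overlap, the exception being cyclophilin. The actin gap moved with a lower 3' signal, from 11.16 and 11.53 to 9.27 and 8.87. Its 5' probe set had 3.90 and 6.26 and then 5.69 and 4.48, so that gap need not reflect RNA integrity. It enters the mean and the covariate, which were not computed without it. The gaps of the other transcripts differed by -0.838 (cyclophilin) to -2.142 (EF1a) between the stages. Within stages, the median difference of tassel emergence replicate 1 minus replicate 2 was -0.38 for secondary wall cellulose, -0.20 for primary wall cellulose synthases, -0.29 for tubulins, -0.20 for monolignol genes, -0.46 for photosynthesis, -0.06 for ribosomal proteins and -0.26 for heat shock genes. That of early silking replicate 1 minus replicate 2, where replicate 2 had the larger gap, was 0.22, -0.02, 0.08, 0.11, 0.32, -0.09 and -0.36 for these lists in the same order. The poly-A control spikes were at 8.52 and 8.14 on the tassel emergence arrays and at 9.06 and 9.62 on the early silking arrays, higher by 1.01 without overlap.

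**Figure D3:**
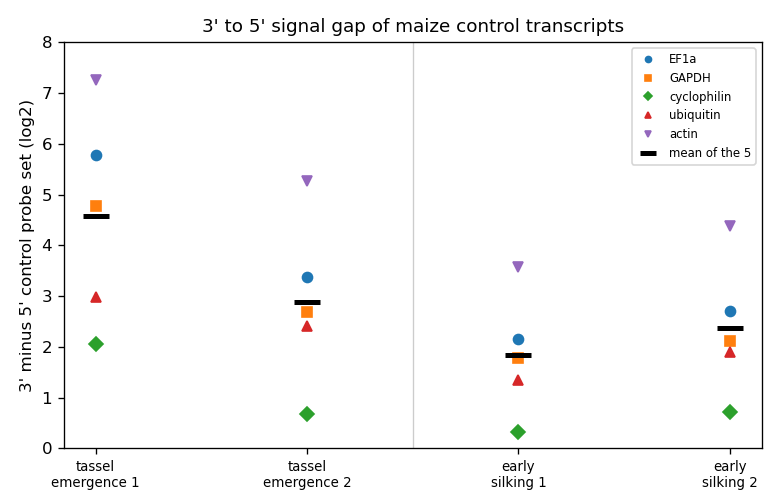
The 3' minus 5' log2 signal of 5 maize control transcripts on each array (symbols) and their mean (bars). The mean is 4.57 and 2.88 on the tassel emergence arrays and 1.84 and 2.37 on the early silking arrays.

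The heat shock and chaperone list fell (median -0.55 over 9 genes, camera adjusted p = 0.0311 preset, adjusted p = 0.804 with an estimated correlation). 7 members were lower and 3 of these passed adjusted over the list alone. The small heat shock protein gene hsp18f had values of 8.47 and 8.53 at tassel emergence and of 3.49 and 4.05 at silking, with 1 array below a log2 value of 4. hsp22 had values of 7.12 and 10.20 at tassel emergence and of 3.03 and 3.41, below that value, at silking. The factor gene hsfb had -1.01, and the chaperonins CPN60I and CPN60II had 0.20 and 0.15. The call of this list ended without tassel emergence replicate 2 (adjusted p = 0.344) and without early silking replicate 1 (adjusted p = 0.154). The cytosolic ribosomal protein list rose (median 0.49 over 10 genes, all higher, adjusted p = 0.0232 preset, adjusted p = 0.683 with an estimated correlation), with RPL19 at 0.98 and RPS10 at 0.58, and no member passed adjusted over the list alone. This call ended without tassel emergence replicate 1 (adjusted p = 0.087) and without early silking replicate 2 (adjusted p = 0.147). The photosynthesis list rose (median 0.55 over 14 genes, 13 higher, adjusted p = 0.038 preset, adjusted p = 0.808 with an estimated correlation), with psaN, a photosystem I subunit, at 0.70 and rbcS, the small subunit of Rubisco, at 0.35, and no member passed adjusted over the list alone. me3, an NADP-malic enzyme, was below a log2 value of 4 at tassel emergence, with values of 2.86 and 3.21, and at 6.37 and 4.85 at silking. The call ended without tassel emergence replicate 1 (adjusted p = 0.441) and without early silking replicate 1 (adjusted p = 0.263).

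The other 12 tested lists did not pass camera. Wall loosening, which holds expansins and a xyloglucan endotransglucosylase, had 6 of 7 members lower and a median of -2.30 (adjusted p = 0.0667). It passed with the replicate number as a block, quantile values, 1 common variance and the wider background. expB6 had -2.69 and was the 1 member to pass adjusted over the list alone, expA4 had values of 9.21 and 6.07 and then of 3.60 and 2.23, and xet1 was at 0.23. The median is that of expB4, at 9.61 and 4.11 at tassel emergence. Leaving out tassel emergence replicate 1 gave an adjusted p of 0.622 and leaving out early silking replicate 2 gave 0.147. This list passed without tassel emergence replicate 2 (adjusted p = 0.0458) and without early silking replicate 1 (adjusted p = 0.0159). Wall structural proteins had a median of 0.34 (adjusted p = 0.377), though 4 of its 6 members carry other names as well, namely PR-1, a pathogenesis-related protein, AGP2 and Agp2, of ADP-glucose pyrophosphorylase, and prcw1, also named as a splicing factor. Floral and inflorescence genes had a median of 0.32 (adjusted p = 0.254) with zap1, a MADS box gene, at 1.19. Aquaporins had a median of -0.21 (adjusted p = 0.453), defence genes 0.68 (0.516), detoxification and redox genes 0.08 (0.587), cell cycle and histone genes 0.08 (0.717), nitrogen and amino acid genes -0.09 (0.722), sucrose and starch genes -0.05 (0.759), kernel storage genes 0.05 (0.759), proteolysis and senescence genes 0.05 (0.935) and ethylene and jasmonate genes -0.07 (0.976), where the second value is the adjusted p. The ethylene and jasmonate list had a negative median and mean (-0.07) and an upward camera direction. The nitrogen list had a negative median with a mean of 0.001 and an upward direction, and the kernel list a positive median with a mean of -0.14 and a downward direction. Adjusted over the list alone, the counts were 2 higher and 1 lower for cell cycle and histone genes, 1 and 1 for sucrose and starch, 2 higher for detoxification and redox, 1 higher each for defence, ethylene and jasmonate, and floral genes, and 1 lower each for aquaporins and kernel storage. The kernel storage member that passed was mez1, a polycomb gene. By their names, mez2 and mez3 are polycomb genes as well and zpu1 is a starch debranching enzyme. The list's zein, gz27, was at -0.49 and its globulin, GLB1, at -0.14, so the list median is not that of storage proteins. The remaining 12 lists had under 5 measured genes and were not tested. The medians were -0.38 for 2 lignin polymerisation genes and 0.71 for 3 genes of the chlorophyll list. They were -1.19 for 4 water deficit genes and -0.89 for 3 gibberellin and brassinosteroid genes. They were 0.12 for 4 genes of the MYB and NAC list and -0.14 for 2 cuticle genes. The 2 genes whose names matched the auxin list, arf1 at -0.06 and abp1 at 0.86, had a median of 0.40. The symbol arf1 alone does not tell an auxin response factor from an ADP-ribosylation factor, so that median may not be one of auxin genes. Amy2 in the MYB and NAC list is a beta-amylase and no NAC gene was measured, and Agpat4 in the sucrose list is an acyltransferase. The chlorophyll list's median of 0.71 is the value of por1, which is a porin. Its other members, por and ChlI, had 0.58 and 0.80. Single genes stood for methyl donors (0.50), flavonoids (0.08) and mitochondrial respiration (-0.26), and the xylan and circadian clock lists had no measured gene. Of these lists, both cuticle genes passed adjusted over the list alone, gl8 higher and plt2 lower. With 1 measured gene, as for methyl donors, that adjustment changes nothing.

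By the rule fixed for named genes, the 12 genes with the smallest p in each direction were taken, since none passed over all probe sets. Each had separate stages, and their limma adjusted p ran from 0.0864 to 0.0946. Lower at early silking were hsp18f, gar2, CesA-8, tub4, LPE1, bk2, ivr2, TIP1-1, CesA12, CesA-2, CesA-9 and an2, and all 12 of these were among the 28 that passed over the named genes. ivr2, a vacuolar invertase, had values of 11.19 and 11.07 at tassel emergence and of 4.06 and 1.78 at early silking, where 1 array was above a log2 value of 4. gar2 was not above that value on either silking array and was at least 66.5-fold lower there, with means of 10.06 and 2.64. LPE1, leaf permease1, was at least 4.71-fold lower and an2, an ent-copalyl diphosphate synthase, at least 4.37-fold lower, both by the same bound. TIP1-1, a tonoplast aquaporin, had a change of -1.99 with an SE of 0.21. Higher at early silking were hda106, acco20, tps6, GST39, dps1, pdrp1, ys1, pdc2, sbe1, nfa101, sps1 and HMT-3. acco20, an ACC oxidase of ethylene synthesis, went from 12.35 ± 0.07 (SD, n = 2) to 13.97 ± 0.04. tps6, a terpene synthase, had a change of 2.68 and GST39, a glutathione transferase, 1.45. hda106, a histone deacetylase, and ys1, an iron-phytosiderophore transporter, were below the floor at tassel emergence and at least 2.46-fold and 3.87-fold higher. dps1 had 1.34, pdrp1, the regulator of pyruvate phosphate dikinase, 1.52, pdc2, a pyruvate decarboxylase, 1.32, sbe1, a starch branching enzyme, 1.35, nfa101 1.18, sps1, a sucrose phosphate synthase, 1.40, and HMT-3, a homocysteine methyltransferase, 1.82. hda106, acco20, tps6, GST39, dps1 and pdrp1 were the 6 higher genes that passed over the named genes. Genes beyond the rule, among them cesa10, tub5, hsp22 and expA4, were chosen after their values were seen.

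Stages did not overlap in 59.7% of tested probe sets, 3758 higher and 2681 lower, where chance gives 33.3% on average. Of these, 690 higher and 1083 lower probe sets differed by at least 2-fold. Probe sets on the same arrays are not independent and the 3' minus 5' gap also moved with stage, so the excess is not a test of stage. At an unadjusted p under 0.05, 1373 were higher and 1306 lower. The median change of all tested probe sets was 0.10, so each change is 0.10 lower when taken relative to it. The list medians were the same with genes below a log2 value of 4 in one stage set at that bound. The camera calls rest on a preset correlation, and none of the 7 held with an estimated one or with fry, for which the smallest adjusted p were 0.629 and 0.0596. The estimated version also has only 2 residual degrees of freedom, which by itself raises p. For wall structural proteins the camera p rose from 0.199 to 0.318, though their estimated correlation of -0.0877 was below the preset 0.01. Its outcome therefore does not tell correlation between genes from a lack of degrees of freedom.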

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

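All tests in this part were chosen after the results were seen. Intervals come from resampling genes or probe sets measured on the same arrays, so they hold no spread between arrays. The control probe sets, which no comparison used, held signals that differed between the arrays. The mean 3' minus 5' gap of 5 maize control transcripts differed by -1.63 on the log2 scale between early silking and tassel emergence. The hybridisation control spikes had a range of 1.8 over the arrays and the poly-A control spikes a range of 1.48. The poly-A spikes were higher at early silking by 1.01 without overlap, and the hybridisation spikes by 0.735 with overlap.

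Suppose the larger gap at tassel emergence had produced the higher wall and tubulin values there. Then, within a stage, the array with the larger gap would also have the higher values. The slope on the gap within stages, which rests mostly on the tassel emergence pair, accounted for a median change of 0.25 over the 29 genes of 4 lists (bootstrap interval 0.125 to 0.499), opposite to the measured median of -0.96. Each stage's pair of arrays alone gave the same sign, 0.27 (interval 0.137 to 0.451) at tassel emergence and 0.23 (interval -0.101 to 0.640) at early silking. A scale left between the deposited arrays would lower all probe sets alike. The 10753 tested probe sets outside these lists had a median change of 0.11 (interval 0.0936 to 0.119), so the deposited values showed no such lowering. Normalization between arrays holds this median near 0, so a scale that it removed was not tested. Plant stage, field conditions at the sampling times and any change of all genes that the normalization removed stay open.

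For the 14 higher photosynthesis genes at early silking the gap accounted for a median change of 0.60 (interval 0.368 to 0.726) against a measured 0.55, so 3' bias, from RNA integrity or from amplification, may account for that list's change. With the gap as a covariate its median was -0.04 and its call ended. For the 10 higher ribosomal protein genes it accounted for 0.01425 (interval -0.141 to 0.20) of 0.49. The ribosomal call also ended with the covariate (adjusted p = 0.117), where the median went from 0.49 to 0.33 and 1 residual degree of freedom was left. Plant stage stays open for both.

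For the 9 lower heat shock genes at early silking the gap accounted for a median change of 0.13 (interval -0.0562 to 2.59), against a measured -0.55. With the gap as a covariate the median was -0.9997 (interval -3.75 to -0.00783) and the list stayed past the threshold (camera, adjusted p = 0.0227). That fit assumes the same slope in both stages, so it does not decide the question. The pairs of arrays went opposite ways beyond the spread between genes, with 0.25 (interval 0.0585 to 2.92) from the tassel emergence pair and -1.09 (interval -1.73 to -0.33) from the early silking pair. The pairs thus gave slopes of opposite sign, and 3' bias cannot be told apart from stage for these genes. Plant stage and the temperature on the sampling days, which the labels do not give, also remain open.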

How the results depend on the processing

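Crossed pairs, the gap covariate, lists checked by name and the wider background were chosen after seeing the data. No probe set passed with the replicate block (smallest limma adjusted p = 0.233, 1594 at an unadjusted p under 0.05), either other filter, quantile or centred values, the trend, a threshold of 0.01, the gap covariate or any array left out. With an array left out, the lone sample is assumed to vary like the other group. With 1 probe set per gene 28 passed. That setting also left out probe sets without a named gene, so 800 were tested. 1 common variance, which ignores differences in spread between genes, called 1045 (300 higher, 745 lower), all at least 2-fold. Deviations of same-numbered arrays correlated at -0.42 across probe sets, and crossed pairs as a block called 357 (88 higher, 269 lower), all at least 2-fold. The 28 genes named by the rule kept their direction wherever they were tested. Of these, 19 passed with 1 common variance and 14 with crossed pairs. Replicate correlations were 0.979 and 0.990 without a filter and 0.914 and 0.958 with the filter at 6, for tassel emergence and early silking.

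Of 19 lists 7 passed, and the values below are adjusted p. With an estimated correlation 0 passed, at 0.683 for ribosomal, 0.804 for heat shock, 0.683 for monolignol, 0.808 for photosynthesis, and 0.629 for each cellulose list and tubulins. With fry 0 passed, at 0.0631, 0.187, 0.119 and 0.432 for the first 4, 0.0596 for each cellulose list and 0.0631 for tubulins. The secondary wall and tubulin lists passed in 15 of 17 settings, all but these. With 1 common variance 4 passed, with calls lost for ribosomal (0.257), monolignol (0.194), photosynthesis (0.0764) and primary wall (0.0641) lists and wall loosening gained (1.6e-06). Photosynthesis was lost with the filter at 6 (0.0814), the gap covariate (0.999) and the wider background (0.0619). Wall loosening was gained with the replicate block (0.00371), quantile values (0.0442) and the wider background (0.0489). With the gap covariate ribosomal proteins were lost (0.117), ethylene and jasmonate was gained upwards (0.0132), and detoxification (0.936), kernel storage (0.341), nitrogen (0.734) and sucrose (0.947) turned direction without passing. Ethylene and jasmonate turned with all probe sets of a gene (0.704) and the wider background (0.906), as did proteolysis with the latter (0.994). Monolignol genes were too few to test in 3 settings, the filter at 6 and without either tassel emergence array.

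With each array left out in turn, 4 to 6 lists passed. The range was 0.0406 to 0.147 for ribosomal, 0.0154 to 0.441 for photosynthesis, 0.00718 to 0.344 for heat shock and 0.0159 to 0.622 for wall loosening. Lists that turned direction without passing ranged from 0.087 to 0.864 for ethylene and jasmonate, 0.344 to 0.782 for kernel storage, 0.486 to 0.912 for nitrogen, 0.540 to 0.912 for sucrose and 0.782 to 0.9995 for proteolysis. Beyond the settings whose construction is named, the cause was not tested.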

Other observations

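The test in this part was chosen after the values were seen, and so were the genes. Among the 28 genes that passed over the named genes, several belonged to no fixed list. The cytosolic glyceraldehyde-3-phosphate dehydrogenase genes gpc3 and gpc4 had changes of -1.68 and -1.91, FAD8, a fatty acid desaturase, -2.08, frk2, a fructokinase, -1.37, and MMT1, a methionine methyltransferase, -1.76. Within the sucrose list, incw1 and sus1 had -1.27 and -0.55, while sps1 had 1.40 on the log2 scale. Glutamine synthetase genes went both ways, with GLN6 at 1.11 and gln2 at 0.80 against gln5 at -1.08, and none of these passed. vp14, which encodes an enzyme of abscisic acid synthesis, had values of 10.04 and 6.23 at tassel emergence and 3.55 and 3.65 at silking. myb42, a MYB factor, was at 6.02 and 4.03 and then at 6.97 and 8.78.

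Some genes differed by more between the arrays of one stage than between the stage means. aos1, allene oxide synthase of jasmonate synthesis, had values of 11.89 and 10.20 on the tassel emergence arrays and 9.83 and 11.05 on the early silking arrays. expB4 had 9.61 and 4.11 at tassel emergence.

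Beta-tubulin genes may have been lower by more than alpha-tubulin genes. The medians were -1.76 over 6 beta genes and -0.50 over 3 alpha genes, and an exact permutation test over the 9 genes, 2-sided, gave p = 0.179, so the hypothesis was not settled. Genes of one family are not independent.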
